A study of Homo sapiens with 4 samples.

How the data were processed

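ChIP-seq libraries for H3K4me1, H3K4me3 and H3K27ac and an input library were made from primary human epidermal keratinocytes kept for 24 hours in 1.8 mM calcium chloride, per the labels' protocols. The labels give single-end sequencing over 50 cycles, and name 1 sample for each mark and 1 for the input. The 4 samples were grouped by the mark in their title. The input has no region list of its own; its reads enter through the counts in the lists of H3K4me3 and H3K27ac. The submitters' processing notes name Bowtie 0.12.7, SICER 1.1 and bedtools 2.11.2 and the genome build hg19, with no step given for any of them. Alignment settings, window and gap sizes, the handling of duplicate reads and the thresholds of the region calls are not given in the sources used here.

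The lists have no header. The deposited H3K4me3 and H3K27ac lists hold, for each region, its bounds, a whole-number count of ChIP reads, a count of input reads, a p-value, a fold (ratio) of ChIP over input and an FDR (q-value). These count columns are raw. In each list the deposited fold equals the ratio of the 2 counts times 1 constant, 2.89 for H3K4me3 and 1.75 for H3K27ac. Where a region has 0 input reads, the fold is computed as if there were 0.25. Read as the ratio of library sizes, the constants put the H3K27ac library at 1.65 times the H3K4me3 library, the H3K4me3 library at 38620760 reads or more, the H3K27ac library at 63644709 or more and the input at 111527771 or more. The fold never lies under 5.00 for H3K4me3 or 2.0 for H3K27ac, and the largest FDR is 1.55e-10 and 0.000249. The authors' p-values and FDR served only to filter. The H3K4me1 list holds bounds and a score of 0 in every row, so neither strength nor threshold can be read from it, nor whether it holds every region called. All widths are multiples of 200 bp. The smallest distance between neighbouring regions is 600 bp for H3K4me1 and 400 bp for the other lists. Each list belongs to 1 library, so no set of regions common to the marks was used. Folds are the authors' values except for joined regions, where they were recomputed from summed counts with the same constant. The 1488 regions with identical bounds in the H3K4me3 and H3K27ac lists all have the same input count.

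Positions are 1-based here; 1 was added to both bounds of the lists, whose end base belongs to the region. Chromosomes 1 to 22 form the main set, X enters as an alternative only, and Y was left out. The gene table at hand is on another build (GRCh38.p14) than the regions, so no region was assigned to a gene or transcription start site. The planned results on transcription start sites and on 18 gene lists were therefore not computed, and regions are named by position. Named regions are the 5 widest of each mark and the 5 of highest fold where a list gives folds; the first 5 joined H3K27ac clusters are also given. This rule was fixed before the data were examined. Enhancer-type regions and clusters were set apart by the absence of H3K4me3, the rule planned for the case without gene positions. It asks for no overlap and sets no distance; distances to the nearest H3K4me3 region were counted after seeing the data, as was the share with H3K4me1 by fold within classes of width.

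A region counted as overlapping when it shared 1 bp or more with a region of the other mark. Chance overlap was taken from 1000 circular shifts of the second list, with 1 random offset per chromosome, inside the span between the first and last region of any mark. The span includes unsequenced stretches, which lowers the shifted shares. A second set of 1000 shifts moved each chromosome by 100 kb to 1 Mb. With 1 library per mark no test across replicates exists, and no p-value is reported, since regions of a genome are not replicates. Shares carry 95% exact binomial (Clopper-Pearson) intervals, counts 95% exact Poisson intervals, and folds of single regions with input reads the binomial interval of the ChIP share. For regions with 0 input reads the fold is given against 3 input reads, the ChIP count taken as it is. Differences between shares carry a normal 95% interval. All cover counting error only, and reads without molecular identifiers are not independent molecules. Differences of medians in the closing section carry bootstrap intervals from 2000 resamples of regions.

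Alternatives were regions at or above the median fold of each list, an FDR 10 times lower, chromosome X added, regions within 600 bp joined, overlaps of 200 bp or 50% of the shorter region, the widest 10% of H3K4me3, joining within 5 or 20 kb, and the top 250 clusters. Added after seeing the data were the shorter shifts, the removal of regions with under 10 input reads per kb, and a fold of 5 or more for H3K27ac. The arithmetic was tested on simulated regions. A list planted to hold 40.0% of the 24062 H3K4me3 regions was recovered at 40.0%, and a list placed at random overlapped 10.5% of them against a shifted mean of 10.2%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.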

Results

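Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map 3 histone H3 modifications in primary human epidermal keratinocytes, the main cell type of the outer skin. The cells had spent 24 hours in medium with 1.8 mM calcium chloride, the standard trigger of keratinocyte differentiation in culture. H3K4me3 is the mark typical of promoters, H3K4me1 of enhancers and promoter flanks, and H3K27ac of active promoters and enhancers. The labels describe 1 library per mark and 1 input library, all from differentiating cells, so the comparisons run between marks within this state. No undifferentiated cells and no replicates were analysed here, and no difference could be set against a spread between replicates. Intervals are 95% exact binomial or Poisson intervals and cover counting error only. Over chromosomes 1 to 22 the listed regions held 38620760 H3K4me3 reads and 33950781 H3K27ac reads, with 5032850 and 13200349 input reads. The H3K4me1 list gives positions without read counts, so its depth is unknown, as is whether it holds every region called. Regions are named by hg19 position.

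H3K27ac was the most widespread of the listed marks, and H3K4me3 covered the least of the genome. The H3K27ac list held 67898 regions over 146 Mb, with a median width of 1400 bp and an interquartile range of 600 to 2600 bp. H3K4me3 formed 24062 regions over 56.3 Mb, with a median width of 2000 bp (interquartile range 1200 to 3000 bp). The 17787 H3K4me1 regions were the widest, at a median of 2800 bp (1600 to 4800 bp), and covered 73.3 Mb. Neighbouring regions lie at least 600 bp apart in the H3K4me1 list and 400 bp in the other lists. Part of the difference in width may therefore come from how regions were joined. H3K4me3 stood higher over input, with a median fold of 20.9 (interquartile range 10.02 to 27.8) against 2.92 for H3K27ac (2.31 to 4.50). Read density in a median region was 620 ChIP reads per kb for H3K4me3 and 142 for H3K27ac, while the input gave 90 and 87.5 reads per kb. The lists start at different folds, 5.00 for H3K4me3 and 2.0 for H3K27ac. With H3K27ac also limited to a fold of 5 or more, 14378 regions over 43.9 Mb were left, fewer than the H3K4me3 regions.

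The broadest domains of H3K4me1 and H3K27ac coincided at 2 places. The widest H3K4me1 region, on chromosome 9 from 137212401 to 137336200, spanned 123.8 kb, and H3K27ac covered 99.4% of it. The widest H3K27ac region, 79.6 kb, began 2.2 kb before it, at 137210201, and ended inside it, at 137289800. It held 26829 ChIP reads (26509 to 27152) and 8787 input reads, a fold of 5.35 (5.22 to 5.48). H3K4me3 covered 9.55% of that H3K27ac region and 7.59% of the H3K4me1 region. On chromosome 17 the second widest H3K4me1 region (79036201 to 79110600, 74.4 kb) likewise shared its place with the second widest H3K27ac region (79052401 to 79115000, 62.6 kb, fold 4.19). The next H3K27ac regions in width lay on chromosome 1 at 2420401 (61.0 kb), chromosome 9 at 139396001 (54.2 kb) and chromosome 8 at 144984201 (49.8 kb). Listed H3K4me1 regions covered 46.9%, 0% and 100% of these; H3K4me1 below the threshold of its list would not be seen. The remaining H3K4me1 regions among the 5 widest lay on chromosome 22 at 46457001 (69.2 kb), chromosome 19 at 39139601 (66.2 kb) and chromosome 3 at 126699001 (65.8 kb).

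The first question was how far the marks occupied the same places. Most H3K4me3 lay under H3K27ac: 21293 of 24062 H3K4me3 regions, 88.5% (88.1 to 88.9), overlapped an H3K27ac region by 1 bp or more. H3K27ac covered 81.5% of the H3K4me3 length. Of the H3K4me1 regions, 85.9% (85.4 to 86.4) overlapped H3K27ac and 62.5% (61.7 to 63.2) overlapped H3K4me3. In the other direction, 31.8% (31.5 to 32.2) of H3K27ac regions overlapped H3K4me3 and 27.8% (27.5 to 28.1) overlapped H3K4me1. Listed H3K4me1 regions lay at 50.7% (50.1 to 51.3) of H3K4me3 regions, a share that would be too low if the H3K4me1 list is partial. Each share was compared with the share left after 1000 circular shifts of the second list along each chromosome. The shifted shares of H3K4me3 regions averaged 11.7% for H3K27ac (range 10.3 to 15.6) and 5.05% for H3K4me1 (4.27 to 6.30). All 6 observed shares exceeded every shift. They were from 5.83 times the shifted mean (H3K27ac regions overlapping H3K4me1) to 10.04 times (H3K4me3 regions overlapping H3K4me1). Against shifts of 100 kb to 1 Mb, which keep the regional density, the excess was smaller, 3.54 to 5.96 times. Limiting H3K27ac to a fold of 5 or more lowered its share among H3K4me3 regions to 47.2% and among H3K4me1 regions to 29.6%. With H3K4me3 and H3K27ac limited to folds at or above their medians, which left 12031 H3K4me3 regions, 31.9% of H3K4me1 regions overlapped H3K4me3.

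**Figure D1:**
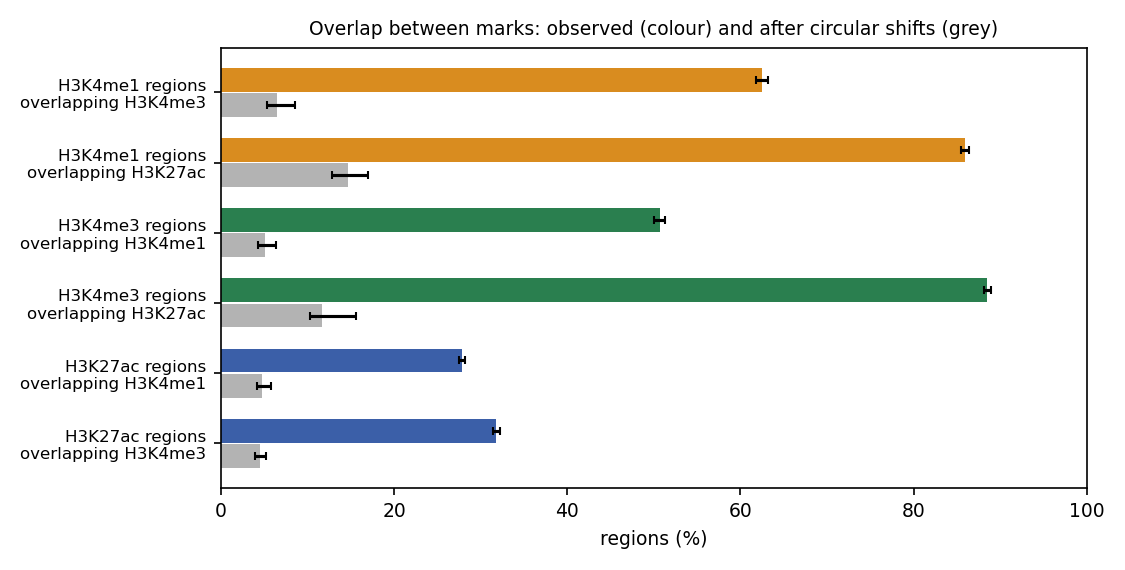
Percent of the regions of each mark that overlap another mark by 1 bp or more (coloured bars, with 95% exact binomial intervals) and the mean after 1000 circular shifts (grey bars, with the lowest and highest shift). Every observed share stands above the highest shift; the largest share is 88.5% (H3K4me3 regions overlapping H3K27ac).

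The combinations at H3K27ac regions separate promoter-type sites, with H3K4me3, from enhancer-type sites, with H3K4me1 and no H3K4me3, in the usual reading of these marks. Acetylation was strongest where H3K4me3 was present. The 10506 H3K27ac regions with H3K4me3 alone had a median fold of 6.92 (interquartile range 3.81 to 9.96) and 336 ChIP reads per kb. The 11099 with both H3K4me1 and H3K4me3 had a median fold of 4.21 (2.95 to 6.48) and were the widest, at 2600 bp. The 7779 with H3K4me1 alone had a median fold of 3.13 (2.46 to 4.25) over 1600 bp. The largest class, 38514 regions or 56.7% (56.3 to 57.1), carried neither a listed H3K4me1 nor an H3K4me3 region and was short and weak, with a median of 800 bp and a fold of 2.51 (2.19 to 3.16). It held 22.2% of the H3K27ac reads, against 36.4% in the class with both marks, 29.8% with H3K4me3 alone and 11.6% with H3K4me1 alone. Median input density ranged only from 83.3 to 96.9 reads per kb over the 4 classes. The classes without H3K4me1 would shrink if the H3K4me1 list is partial. H3K4me3 is listed only from a fold of 5.00, so the classes without it may hold weaker H3K4me3. The composition also depended on the fold minimum. At a fold of 5 or more, 13.5% of the H3K27ac regions had neither mark, 47.6% had H3K4me3 alone, 30.4% had both and 8.53% had H3K4me1 alone. With H3K4me3 and H3K27ac both limited to folds at or above their medians, 22.3% had H3K4me1 alone and 43.9% neither. That setting also cuts the H3K4me3 regions from 24062 to 12031. H3K27ac regions over the dropped ones then count as without H3K4me3, so the larger share cannot be read as a gain in enhancer-type sites. The number with H3K4me1 alone was 7585, against 7779 in the full lists.

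**Figure D2:**
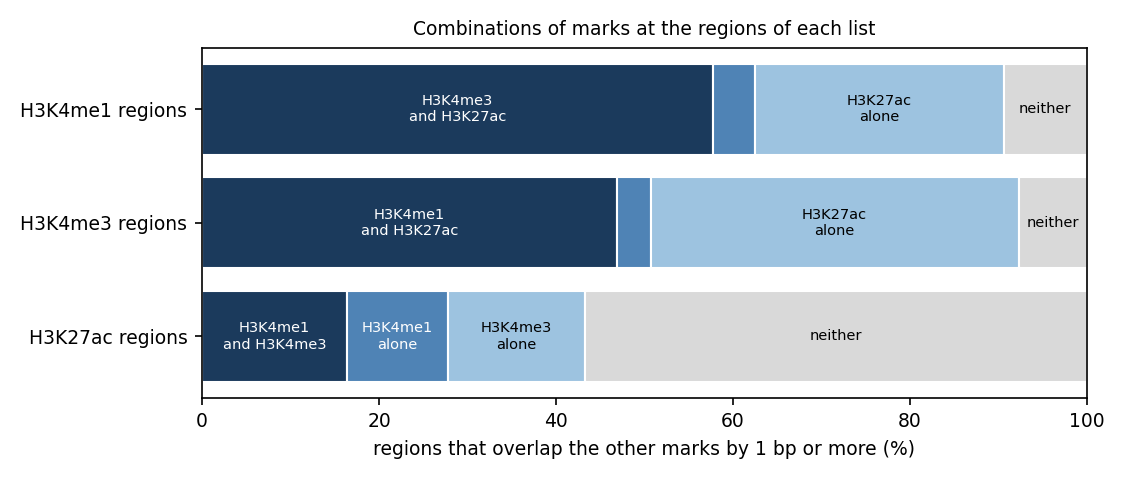
Percent of H3K4me1, H3K4me3 and H3K27ac regions by which of the other 2 marks they overlap by 1 bp or more; each bar adds up to all regions of that mark. The narrow unlabelled segments are H3K4me1 regions with H3K4me3 alone (4.67%) and H3K4me3 regions with H3K4me1 alone (3.79%), and 56.7% of H3K27ac regions have neither mark.

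Seen from the methylation marks, sites without a listed H3K27ac region were few and small. This holds for the H3K27ac list as it stands, from a fold of 2.0. At a fold of 5 or more, H3K27ac overlapped only 47.2% of H3K4me3 and 29.6% of H3K4me1 regions. Of the H3K4me3 regions, 46.9% (46.3 to 47.5) carried H3K4me1 and H3K27ac, and 41.6% (41.0 to 42.2) carried H3K27ac alone, with median folds of 21.04 and 23.8. The 1856 regions (7.71%) with neither mark had a median width of 800 bp and a fold of 7.32 (interquartile range 5.88 to 10.4). H3K4me3 regions with H3K4me1 but no H3K27ac numbered 913 (3.79%). They too were low, with a median fold of 10.2. The 1856 and 913 regions held 0.863% and 0.935% of the H3K4me3 reads. Among H3K4me1 regions, 57.8% (57.1 to 58.5) carried both other marks and 28.1% (27.5 to 28.8) carried H3K27ac alone. The 1670 H3K4me1 regions with neither, 9.39% (8.96 to 9.83), had a median width of 1000 bp. The share of H3K4me1 regions with H3K27ac rose with width, from 39.4% (36.9 to 41.95) below 1 kb to 300 of 300 at 20 kb or more. A wider region is also more likely to overlap by chance. Shifted shares by width of the H3K4me1 regions are not given here, so the rise cannot be set against chance.

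H3K4me1 was then placed relative to H3K4me3 within the 13052 H3K4me3 regions of 2 kb or more. In the 6324 of them that touched H3K4me1, H3K4me1 mostly lay over the middle of the H3K4me3 region and in part also outside its edges. Points outside the edges can lie in a separate region of a mark. The centre lay inside an H3K4me1 region in 97.7% and inside an H3K27ac region in 96.6%. The H3K4me1 list gives no read counts and its smallest gap is 600 bp. A short dip in H3K4me1 at the centre would therefore not be seen. At 1 kb outside the edges, H3K4me1 was present in 43.7% and 44.2% (lower and higher coordinate side) and H3K27ac in 34.1% and 34.7%. The 6728 H3K4me3 regions without H3K4me1 had H3K27ac at the centre almost as often, 94.8%, but at 1 kb outside the edges in 13.7% on either side. At 10 kb the shares with H3K27ac were still 25.3% and 24.1% around regions with H3K4me1, and 11.3% and 12.1% around those without.

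**Figure D3:**
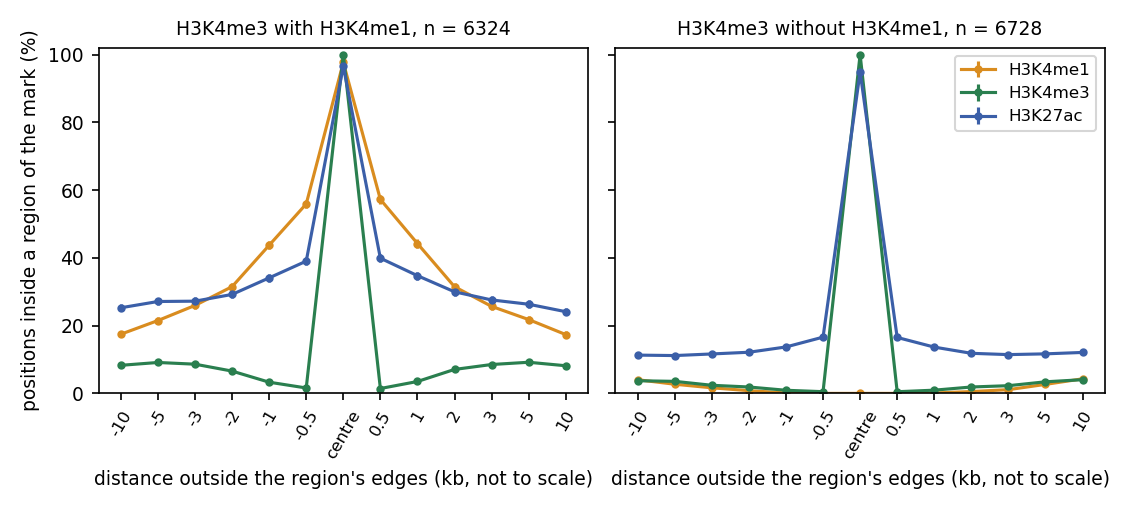
Percent of H3K4me3 regions of 2 kb or more whose centre, or a point at the given distance outside either edge (kb, unevenly spaced axis), lies inside a region of each mark; the left panel shows the 6324 regions with H3K4me1 and the right panel the 6728 without, with 95% exact binomial intervals mostly smaller than the points. H3K27ac was present outside the edges more often on the left, at 1 kb in 34.1% and 34.7% against 13.7%. Such points can lie in a separate H3K27ac region. At 10 kb the shares with H3K27ac were still 25.3% and 24.1% against 11.3% and 12.1%. The absence of H3K4me1 at the centre on the right follows from how these regions were chosen. Outside the edges the choice excludes only H3K4me1 regions that also reach the H3K4me3 region. H3K4me1 lay there at 0.12% on either side at 1 kb, and at 4.03% and 4.30% at 10 kb.

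Enhancer-type sites were counted as H3K27ac regions that overlapped H3K4me1 and no listed H3K4me3 region. H3K4me3 is listed only from a fold of 5.00, so sites with weaker H3K4me3 count as without it. There were 7779 with the H3K4me1 regions listed, covering 19.8 Mb and 13.5% of the H3K27ac length. No distance from H3K4me3 was required: 6274 of them, 80.7% (79.8 to 81.5), lay 2.5 kb or more from the nearest H3K4me3 region, at a median distance of 12.6 kb for all 7779. They lay closer to H3K4me3 than the 46293 H3K27ac regions without H3K4me3 as a whole, of which 90.2% (89.97 to 90.5) lay 2.5 kb or more away, at a median of 21.2 kb. Their number fell to 5523 with regions within 600 bp joined, and to 1226 when H3K27ac was limited to a fold of 5 or more. Among H3K27ac regions of 1 kb or more without H3K4me3, the share with H3K4me1 rose with the H3K27ac fold at every step. It was 13.7% (13.1 to 14.4) of 10631 regions at folds of 2 to 2.5, 36.3% (34.3 to 38.3) of 2321 at 4 to 5, and 53.5% (49.7 to 57.2) of 705 at 6 to 8. It reached 79.6% (65.7 to 89.8) of the 49 regions at 10 or more. Wider regions had H3K4me1 more often, but the rise was also seen at like width. From folds of 2 to 2.5 to folds of 5 or more, the share went from 11.7% (10.9 to 12.5) to 39.9% (36.1 to 43.7) at 1 to 2 kb and from 16.3% (13.6 to 19.2) to 61.5% (56.0 to 66.9) at 5 to 10 kb. Distance to transcription start sites was not used here, so unmarked promoters are not excluded from this class.

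**Figure D4:**
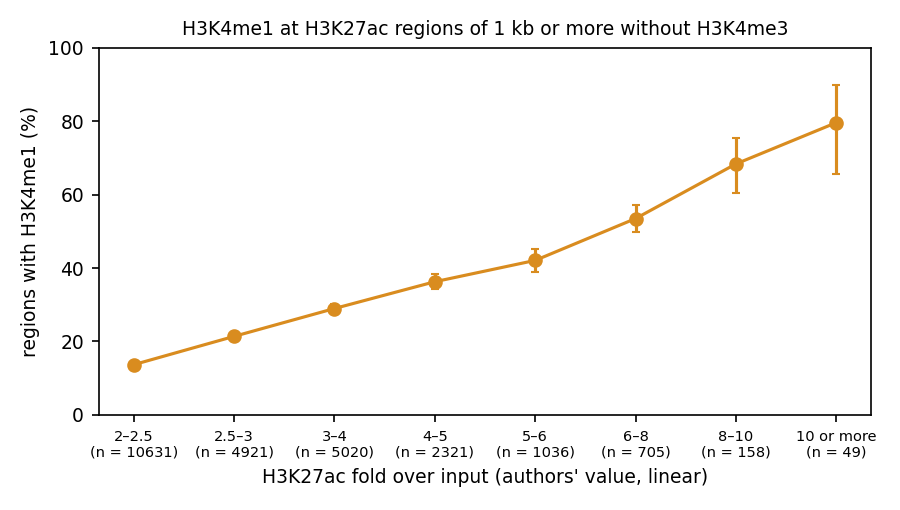
Percent of H3K27ac regions of 1 kb or more without H3K4me3 that overlap H3K4me1 (y axis), by the authors' H3K27ac fold over input (x axis, classes of uneven size); bars are 95% exact binomial intervals and n is the number of regions. The share rises from 13.7% to 79.6%.

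Broad H3K4me3 domains were taken as the widest 5% of the H3K4me3 list, 1129 regions of more than 5200 bp. All but 1 of them overlapped H3K27ac, 99.9% (99.5 to 99.998), against 87.9% (87.5 to 88.3) of the 22933 other regions. The lower share of the others came from short regions: it was 56.0% (54.4 to 57.7) below 1 kb and 86.4% (85.6 to 87.2) at 1 to 2 kb, but 97.8% (97.4 to 98.2) at 2 to 3 kb and 99.4% (99.1 to 99.6) at 3 to 5 kb. After the shifts the shares averaged 20.4% for the widest and 11.3% for the others. The difference of 12.0 points depended on the folds taken: it was 39.0 points with H3K27ac at a fold of 5 or more and 6.58 at or above the median fold of both lists. The median H3K4me3 fold was 22.7 (interquartile range 17.8 to 27.03) in the widest and 20.8 (9.64 to 27.8) in the others, and the median read density was 679 and 614 reads per kb. The 1129 regions held 14.5% of the H3K4me3 reads. H3K4me1 lay at 60.8% (57.8 to 63.6) of the widest and 50.2% (49.6 to 50.9) of the others, a difference of 10.6 percentage points. The shifted shares averaged 8.61% and 4.89%. The difference was 1.81 points (-0.32 to 3.94) when the widest 10% were taken, and regions of 1 to 2 kb had H3K4me1 as often, 61.5% (60.4 to 62.6). The widest region lay on chromosome 7 from 27178801 to 27214600 (35.8 kb). It held 35652 ChIP reads (35283 to 36024) and 3443 input reads, a fold of 29.9 (28.9 to 31.0). H3K4me1 covered 98.3% of it and H3K27ac 94.4%. Over it H3K27ac was broken into 4 regions with folds of 3.57, 10.5, 14.6 and 6.14 from the lower to the higher coordinate. The next in width were on chromosome 6 at 10402601 (19.2 kb, fold 31.8), chromosome 1 at 16467801 (18.8 kb, 15.2), chromosome 8 at 145003001 (18.6 kb, 24.6) and chromosome 1 at 156083201 (17.6 kb, 13.8). H3K4me1 covered all of these 4.

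**Figure D5:**
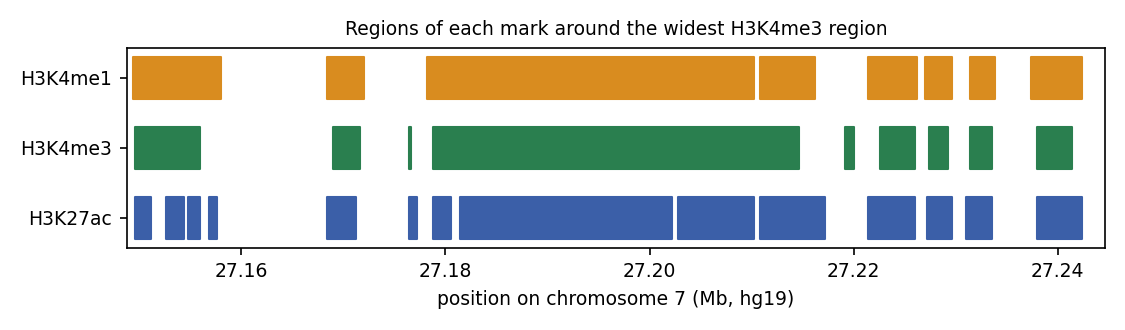
Regions of the 3 marks on chromosome 7 (x axis, position in Mb, hg19), from 30 kb before to 30 kb after the widest H3K4me3 region; each block is 1 listed region, to scale. A 35.8 kb H3K4me3 block lies under a 32.0 kb and a 5.4 kb H3K4me1 block and 4 H3K27ac blocks.

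Clusters of acetylation were built by joining H3K27ac regions without a listed H3K4me3 region that lay within 10 kb of each other. The 46293 regions gave 25484 clusters, of which 16168 were a lone region. The 500 clusters with the most reads had a median span of 40.3 kb (interquartile range 29.0 to 53.9) and a median of 7 regions, and held 24.1% of the reads of all clusters. With H3K27ac at a fold of 5 or more there were 2784 clusters, and the top 500 held 62.0% of the reads. Without that limit, 423 of the top 500 of the 25484 clusters overlapped H3K4me1, 84.6% (81.1 to 87.7). The share was 20.3% (19.8 to 20.8) in the other 24984, whose median span was 1.6 kb. The difference in span makes overlap more likely for the top 500. Joining could bridge H3K4me3: the span of 141 of the 500, 28.2% (24.3 to 32.4), held an H3K4me3 region between the joined ones. The highest ranked cluster lay on chromosome 14 from 93391601 to 93575400, with 24 regions and 29561 reads at a fold of 3.51. It was followed by chromosome 10 from 105462201 to 105604600 (23330 reads, 3.72), chromosome 22 from 36677801 to 36777000 (23279 reads, 4.82), chromosome 11 from 12177201 to 12313200 (21376 reads, 3.90) and chromosome 11 from 119518801 to 119593600 (18308 reads, 5.01). H3K4me1 regions covered 52.4, 60.2, 63.8, 10.8 and 52.4 kb of these 5.

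The regions with the highest fold over input, as listed by the authors, were short and rested on almost no input reads. The 5 highest H3K4me3 folds belonged to regions of 400 bp with 35 to 88 ChIP reads and 0 input reads. They lay on chromosome 9 at 45441401, chromosome 2 at 110552001 and 111334201, chromosome 15 at 84842001 and chromosome 16 at 18573201. The authors list folds of 404 to 1016 for them. Against the limit of 3 reads that a count of 0 allows, and with no error on the ChIP count, the folds were at least 33.7 to 84.7. None of the 5 overlapped H3K27ac or H3K4me1. The highest H3K27ac fold, 120.9, was a 400 bp region on chromosome 2 at 87304001 with 69 ChIP reads and 1 input read. Its counting interval ran from 20.99 to 4844. The next 4 had 29 to 68 ChIP reads and 1 or 2 input reads over 200 bp, on chromosome 10 at 106204801, chromosome 12 at 121308001, chromosome 2 at 101977001 and chromosome 5 at 177099001.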

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

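The limit of H3K27ac to a fold of 5 or more, the shifts of 100 kb to 1 Mb and the removal of regions with under 10 input reads per kb were tests chosen after the results had been seen. Few input reads limit the folds of 80 H3K4me3 and 19 H3K27ac regions, which have under 10 input reads per kb for a cause that was not tested, and the H3K4me1 list gives neither depth nor strength, so a stricter H3K4me1 list was not made. Of 170 values recomputed, 111 stayed within the reported interval or within 1.5 times the reported number. The sign changed in 0, but only the differences between the widest and other H3K4me3 regions could change sign. The tally is no measure of stability, since 27 of the 170 were identical to the reported value, many because the setting does not act on them. An overlap of 200 bp is met by every overlap of 1 bp, as all regions lie on a grid of 200 bp. An FDR 10 times lower, an overlap of 50% of the shorter region and the removal of low-input regions moved none of the values they act on. The FDR limit removed only 18 H3K4me3 and 551 H3K27ac regions, and the low-input limit 80 and 19. These 2 settings could therefore hardly move a value. Alternatives on transcription start sites and gene lists were not run. The removal or joining of regions is itself the change in the settings below; no further cause was tested.

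With H3K27ac at a fold of 5 or more, 14378 H3K27ac regions over 43.9 Mb were left. They overlapped 29.6% of H3K4me1 and 47.2% of H3K4me3 regions. Of them, 38.9% overlapped H3K4me1 and 78.0% H3K4me3; 30.4% had both, 8.53% H3K4me1 alone, 47.6% H3K4me3 alone and 13.5% neither. The enhancer-type class fell to 1226, and the widest H3K4me3 regions exceeded the others in H3K27ac by 39.0 points. There were 2784 clusters; the top 500 held 62.0% of the reads, and 74.2% of them had H3K4me1. At or above the median fold of both lists, 12031 H3K4me3 regions (34.4 Mb) and 34028 H3K27ac regions (90.3 Mb) remained. H3K4me1 regions then overlapped H3K4me3 in 31.9% and H3K27ac in 62.4%. H3K4me3 regions overlapped H3K4me1 in 48.2% and H3K27ac in 93.2%, and H3K27ac regions overlapped H3K4me1 in 37.7% and H3K4me3 in 33.9%. The H3K27ac classes became 15.4% both, 22.3% H3K4me1 alone, 18.5% H3K4me3 alone and 43.9% neither. H3K27ac regions that overlapped only dropped H3K4me3 regions count as without H3K4me3 in these classes, and could enter the clusters. The widest regions exceeded the others in H3K27ac by 6.58 points, and 14983 clusters were left, 92.8% of the top 500 with H3K4me1.

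With X added, H3K4me1 regions overlapped H3K4me3 in 61.3% and H3K27ac in 84.2%, H3K4me3 regions H3K4me1 in 51.5%, and H3K27ac regions H3K4me1 in 28.6% and H3K4me3 in 32.2%. The H3K27ac classes were 16.8% both, 11.8% H3K4me1 alone and 56.0% neither. Joining regions within 600 bp gave H3K27ac regions 35.0% overlap with H3K4me3 and classes of 17.98% both, 9.55% H3K4me1 alone, 17.0% H3K4me3 alone and 55.5% neither. It also gave a difference of 14.0 points in H3K4me1 between the widest and other H3K4me3 regions, and H3K4me1 at 79.4% of the top clusters. Taking the widest 10% of H3K4me3 changed the differences to 12.6 points for H3K27ac and 1.81 for H3K4me1. Clusters joined within 20 kb had H3K4me1 in 90.8% of the top 500, within 5 kb in 76.2%, and the top 250 in 88.8%, with 16.1% of the reads. Against shifts of 100 kb to 1 Mb, the excess of overlap was 5.92 times for H3K4me1 regions with H3K4me3 and 3.70 with H3K27ac. It was 5.96 for H3K4me3 regions with H3K4me1 and 4.75 with H3K27ac, and 3.54 and 4.51 for H3K27ac regions with H3K4me1 and H3K4me3.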

Other observations

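The marks were spread unevenly over the chromosomes. All 3 were densest on chromosome 19, with 63.8 H3K27ac, 28.9 H3K4me3 and 20.9 H3K4me1 regions per Mb of the span that holds regions. Chromosome 4 had the lowest density of each, at 14.7, 5.00 and 3.29. Chromosomes 22 and 17 came next after 19, with 54.0 and 43.7 H3K27ac regions per Mb. The 500 top clusters of H3K27ac without H3K4me3 were ordered differently: chromosome 22 led with 90.2 clusters per 100 Mb (31 clusters), followed by chromosome 17 with 51.8 (42 clusters) and chromosome 19 with 45.9 (27 clusters). These are counts from 1 library per mark.

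The folds of H3K4me3 and H3K27ac could be set side by side in the 1488 regions with identical bounds in both lists. The median fold was 22.3 for H3K4me3 and 4.44 for H3K27ac. Each fold comes from its own immunoprecipitation, and the lists start at folds of 5.00 and 2.0, so the medians do not measure which mark is stronger. Across these regions, which are not independent replicates, the folds were related, with a Pearson r of 0.59 on the log2 scale and a Spearman rho of 0.63. Both folds share the same input counts as denominator, so part of the relation is built in.

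The tests below on the strength of H3K4me1, on loss of regions and on input reads were chosen after the values had been seen; the other 3 were written down before. The design has no second condition, so no biological explanation that rests on a difference between conditions was tested.

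Most wide H3K27ac domains were either nearly covered by H3K4me1 or lacked it. Of 1363 H3K27ac regions of 10 kb or more, 438 (32.1%) had no H3K4me1 region, 631 were covered by 90% or more, and 294 lay between. That H3K4me3 takes the place of H3K4me1 in them as a set is argued against. Median H3K4me3 cover was 6.76% without and 30.8% with H3K4me1, a difference of -24.1 points (-31.7 to -19.2). The groups were not matched on H3K27ac fold, and H3K4me3 is listed only from a fold of 5.00. Replacement at some of the regions is therefore not excluded. Random loss of regions from the H3K4me1 list as the whole cause is also argued against, because at 10 to 20 kb the share with H3K4me1 was 42.0 points higher in the 388 regions of highest H3K27ac fold (84.5%) than in the 388 of lowest (42.5%). A minimum on H3K4me1 strength may have removed them. The regions without H3K4me1 had a lower H3K27ac fold (medians 2.83 and 4.58, difference -1.75, -1.96 to -1.55). This is the relation between H3K27ac fold and H3K4me1 of the preceding test seen from the other side, and no separate evidence. Truly lower H3K4me1 at these sites predicts the same and stays open, since the list gives no strengths.

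H3K4me1 was less frequent at H3K4me3 regions of high fold. Among H3K4me3 regions of 2 kb or more it lay at 68.8% (66.2 to 71.3) of the 1306 with the lowest folds, 36.4% (33.8 to 39.1) of the 1305 with folds of 26.96 to 28.9 and 52.6% (49.9 to 55.3) of the 1306 with the highest folds. Differences in region width are argued against as the whole cause, since within 2 to 3 kb the share still changed by -15.1 points, from 61.8% of the 2446 regions of lowest fold to 46.7% of the 2446 of highest fold. A candidate explanation is that H3K4me1 recedes from the centre of strongly marked H3K4me3 regions. Among those of 2 to 3 kb with H3K4me1, the share over the middle base changed by -1.42 points at high fold, from 99.4% (98.9 to 99.7) to 97.99% (96.99 to 98.7). The intervals lay apart in the direction the explanation predicts, which meets the criterion written down before. The explanation stays open all the same, because both shares lie near their ceiling, a limit the criterion did not name. Short dips in H3K4me1 inside a listed region would also not be seen.

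The highest folds over input differ between the lists. For the 50 highest H3K4me3 folds, few input reads in the denominator may be the source: input density was 5.56% of the list median, and ChIP density only 23.6% of it. Choosing regions by their ratio itself favours a low input density, and may also favour regions with few reads of both kinds. The low ChIP density is therefore no independent support. For the 50 highest H3K27ac folds, input density was 17.1% of the list median and ChIP density 151% of it. Choosing regions by their ratio can also favour a high ChIP density, so how far the input accounts for these folds stays open. Of these 50, 38 overlapped H3K4me3, while 18 of the 50 H3K4me3 regions overlapped H3K27ac. Whether near-identical copies of sequence share reads at these places was not tested.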
